A study of Gallus gallus with 16 samples.

How the data were processed

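RNA of the pituitary gland, the ovary and the hypothalamus was sequenced from hens of the Luhua breed, a Chinese local chicken, at 300 days of age. Per the labels' protocols, 856 birds were ranked by the number of eggs laid, and the 200 with the most and the 200 with the fewest eggs made up the high (HEP) and low (LEP) egg production groups. Total RNA was isolated with the RNeasy Mini Kit and sequenced on an Illumina HiSeq 2500, per the labels' protocols and the series design. The 16 libraries analysed come from 6 hens, hens 1, 2 and 3 being HEP and hens 4, 5 and 6 LEP. The title number and a code in the labels tie the tissues of a hen together, so replicate numbers are hen numbers. Ovary and hypothalamus of hen 2 were not analysed here.

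The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled to library size), with 17108 rows and 1 column per library. FPKM values are already divided by gene length and library size. The aligner, the quantification tool, the genome build and the annotation are not given in the sources used here. Each row carries an Ensembl gene identifier without a symbol. The reference gene table used here (assembly GRCg7b) holds 25635 genes and 0 Ensembl identifiers, so 0 of 17108 identifiers were matched to a symbol. The files do not pair identifiers with names, and genes are therefore given by identifier, at most 2 higher and 2 lower per comparison. The lists of genes by symbol that had been fixed before the data were examined (hormones and receptors, steroidogenesis, cell type markers and others) and the test for carry-over of neighbouring tissue by markers could not be run.

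The number of reads per library is unknown. The low values were searched for steps of whole reads by taking, for pairs of libraries of a tissue, the ratio of genes under 0.3 FPKM in both. The share of ratios within 0.05 (log2) of the commonest ratio was 5.01% to 20.2%, too low to recover reads. No interval from counting error is given for that reason. A value of exactly 0 can be a failed estimate in such a table, since genes at high FPKM in other libraries are also listed at 0. Reads per gene are unknown and FPKM is divided by gene length, so a high FPKM need not mean many reads. Genes with such zeros are described as listed at 0 with each library's value. Fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes.

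Comparisons were made with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend) on log2(FPKM + 1), for genes with a mean FPKM of at least 1 over the libraries of the fit. P values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. HEP was compared with LEP in each tissue alone. A model of all 16 libraries with 6 group means gave the mean HEP minus LEP difference of the 3 tissues. Hen was a random effect there (correlation 0.00863 between libraries of a hen). This is a single value for all genes and near 0, so the p values of this mean also treat the tissues of a hen as nearly independent. The same group means without a hen effect gave the differences of the HEP effect between tissues, and the tissue contrasts. The main p values of these last 2 kinds of contrast therefore treat the tissues of a hen as independent. Tissue contrasts also required an absolute log2 difference of at least 1. Hens are nested in the production groups, so hen as a fixed block was possible for the last 2 kinds of contrast only. The pairing comes from the labels. Deviations from group means correlated between the pituitary and the ovary of a hen with r between -0.060 and 0.208 across genes over 5 hens, between pituitary and hypothalamus with r between -0.074 and 0.059, and between hypothalamus and ovary with r between -0.080 and 0.0035. The correlation of HEP minus LEP differences between tissues was computed across genes and set against the 10 splits of the 5 hens with all tissues. Named genes were those past the threshold with no overlap between HEP and LEP libraries and the largest differences. Places left were filled with the lowest unadjusted p, at an absolute log2 difference of at least 1 and again with no overlap. For the other contrasts the named genes were those of lowest adjusted p or, for tissue contrasts, of largest difference.

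Sets of tissue-enriched genes were added after the data were examined. A gene entered a set with a mean of at least 5 FPKM in a tissue, a log2(mean + 1) at least 3 above both other tissues, and no overlap of libraries, in the 13 libraries that list most genes above 0. Sets were tested with camera (preset correlation 0.01), with an estimated correlation, and with fry.

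The tests were tried on simulated data with the means and spread of each gene and 200 changed genes. At a 4-fold change the pituitary fit of 11820 genes recovered 91.5% of them and the ovary fit of 12326 genes 63%. At a 2-fold change the pituitary fit recovered 24.5% and the ovary fit 0%. The hypothalamus fit of 10703 genes recovered 0% even at a 16-fold change. For the 12648 genes of the 16-library model, 16-fold changes were recovered to 96% for the mean of tissues and to 86.5% for pituitary against ovary. For the HEP effect in pituitary minus ovary the share was 45.5%.

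Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, scaling by median ratio, quantile normalization, array weights, no trend, all 16 libraries in a single fit, a threshold of 0.10, hen as block, and leaving out each library or hen. Without genes that switch between 0 and at least 10 FPKM within a tissue, and without 3 hypothalamus libraries that list few genes above 0, the comparisons were repeated as alternatives added after the data were examined. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for the remaining steps.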

Results

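The series asks which genes of the hypothalamus, pituitary and ovary, the organs that control laying, differ between hens with high and low egg production. The pituitary was represented by 3 HEP and 3 LEP libraries, and the ovary and the hypothalamus by 2 HEP and 3 LEP libraries each. In 13 libraries, 13713 to 14356 of 17108 genes were listed above 0 FPKM. In 3 hypothalamus libraries, HEP 1, LEP 5 and LEP 6, this number was 6186, 6843 and 6465. Pituitary libraries correlated across genes with r of 0.968 to 0.982 on the log2(FPKM + 1) scale, ovary libraries with 0.960 to 0.979, and the hypothalamus libraries HEP 3 and LEP 4 with 0.964. The 3 hypothalamus libraries with few genes correlated with HEP 3 and LEP 4 at 0.687 to 0.709, and with pituitary or ovary at 0.546 to 0.607. No libraries were identical. A group of 3 genes took 47.3% to 75.1% of the summed FPKM of each library.

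**Figure D1:**
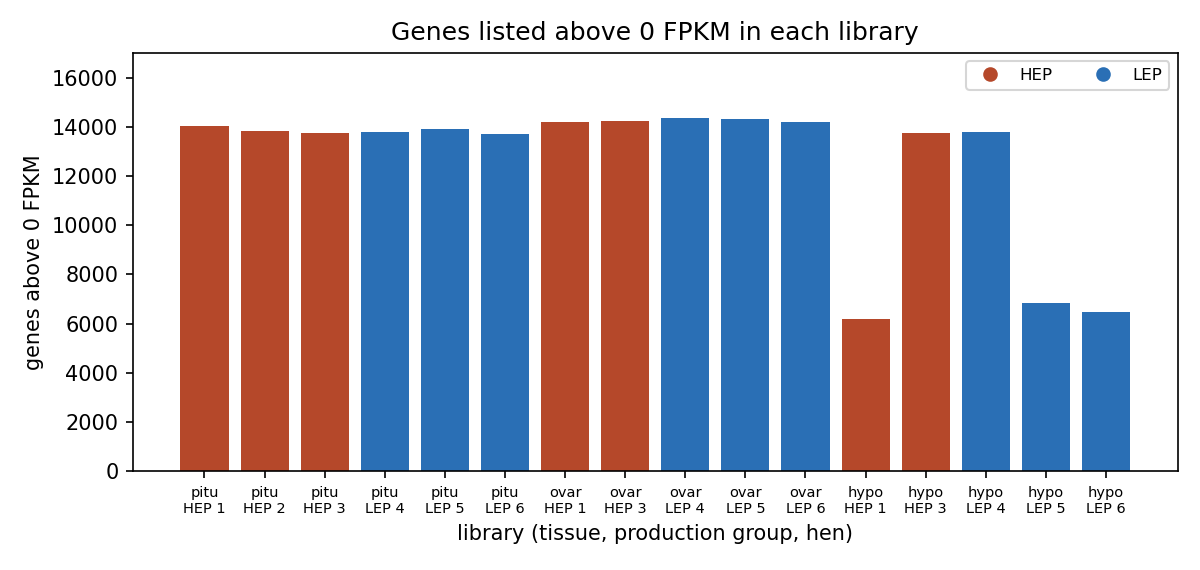
Number of genes listed above 0 FPKM (vertical axis) in each of the 16 libraries, by tissue, production group and hen. The hypothalamus libraries HEP 1, LEP 5 and LEP 6 list 6186, 6843 and 6465 genes, the other 13 list at least 13713.

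ENSGALG00000000249 was the gene with the largest excess in pituitary over ovary, at 17037 to 54546 FPKM in the 6 pituitaries and 0.63 to 2.68 FPKM in the 5 ovaries (log2 difference 13.55, SE 0.35, adjusted p = 8.05e-11). ENSGALG00000027090 had the largest excess in ovary, at 608 to 1373 FPKM, with at most 0.25 FPKM in pituitary (log2 difference -9.55, SE 0.33, adjusted p = 7.89e-10) and at most 3.20 FPKM in hypothalamus (log2 difference of hypothalamus against ovary -8.60, SE 0.35, adjusted p = 2.01e-09). ENSGALG00000000112 stood at 11639 to 51780 FPKM in the 5 hypothalamus libraries, those with few genes included, and at no more than 10.2 FPKM in pituitary and 8.15 FPKM in ovary. Its log2 difference was 11.65 (SE 0.66, adjusted p = 1.62e-08) against ovary and -11.84 (SE 0.63, adjusted p = 1.46e-08) for pituitary against hypothalamus. ENSGALG00000028564, at 17837 to 30761 FPKM in pituitary and 1.00 to 13.3 FPKM in hypothalamus, had the largest excess over the hypothalamus (log2 difference 11.64, SE 0.38, adjusted p = 5.97e-10).

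Of 12648 genes tested with limma, 990 were higher and 1951 lower in pituitary than in ovary. Between pituitary and hypothalamus 3780 were higher and 899 lower in the pituitary, and between hypothalamus and ovary 791 were higher and 4967 lower in the hypothalamus. Without the 3 hypothalamus libraries with few genes, the numbers became 1515 and 3209 for pituitary against ovary, 2529 and 1975 for pituitary against hypothalamus, and 1615 and 3940 for hypothalamus against ovary. Leaving out hen 1, whose hypothalamus is 1 of these libraries, gave 2542 genes for pituitary against hypothalamus and 3127 for hypothalamus against ovary.

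In the pituitary, no gene passed the threshold between HEP and LEP hens. The gene nearest to it was ENSGALG00000020982, at 9.97 ± 5.39 FPKM in HEP (SD, n = 3) and 0.166 ± 0.092 FPKM in LEP (SD, n = 3), higher in 3 of 3 HEP libraries (log2 difference 3.10, SE 0.35, adjusted p = 0.1004). This gene was listed at 0 in every ovary and hypothalamus library. ENSGALG00000014843 stood at 10.03 ± 2.25 FPKM in HEP and 3.74 ± 0.94 FPKM in LEP (log2 difference 1.22, SE 0.22, adjusted p = 1.00). ENSGALG00000009808 had 4.47 ± 0.54 FPKM in HEP and 17.8 ± 8.06 FPKM in LEP (log2 difference -1.67, SE 0.33, adjusted p = 1.00), and ENSGALG00000004298 had 8.61 ± 6.29 and 29.1 ± 5.08 FPKM (log2 difference -1.82, SE 0.37, adjusted p = 1.00). In these 4 genes, HEP and LEP libraries did not overlap, but the rule for naming genes required this, so it is no result. Chance gives it for 10% of genes with 3 against 3.

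With limma, 0 of 11820 genes passed in the pituitary, and 244 had an unadjusted p under 0.05, where 591 are expected by chance. ENSGALG00000020982 passed with a pseudocount of 0.1 (adjusted p = 0.0213), in the fit of all 16 libraries (adjusted p = 0.00131), without HEP 1 (adjusted p = 0.000572), without HEP 2 (adjusted p = 0.0452) and without genes that switch between 0 and at least 10 FPKM (adjusted p = 0.00418). In the fit of all 16 libraries its SE is 0.30 instead of 0.35. The ovary and hypothalamus libraries, all listed at 0 for this gene, add no spread there. Over all its alternatives the adjusted p lay between 0.000572 and 0.991. ENSGALG00000004298 passed without HEP 1 (adjusted p = 0.00305) and ENSGALG00000009808 without LEP 4 (adjusted p = 0.0157).

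**Figure D2:**
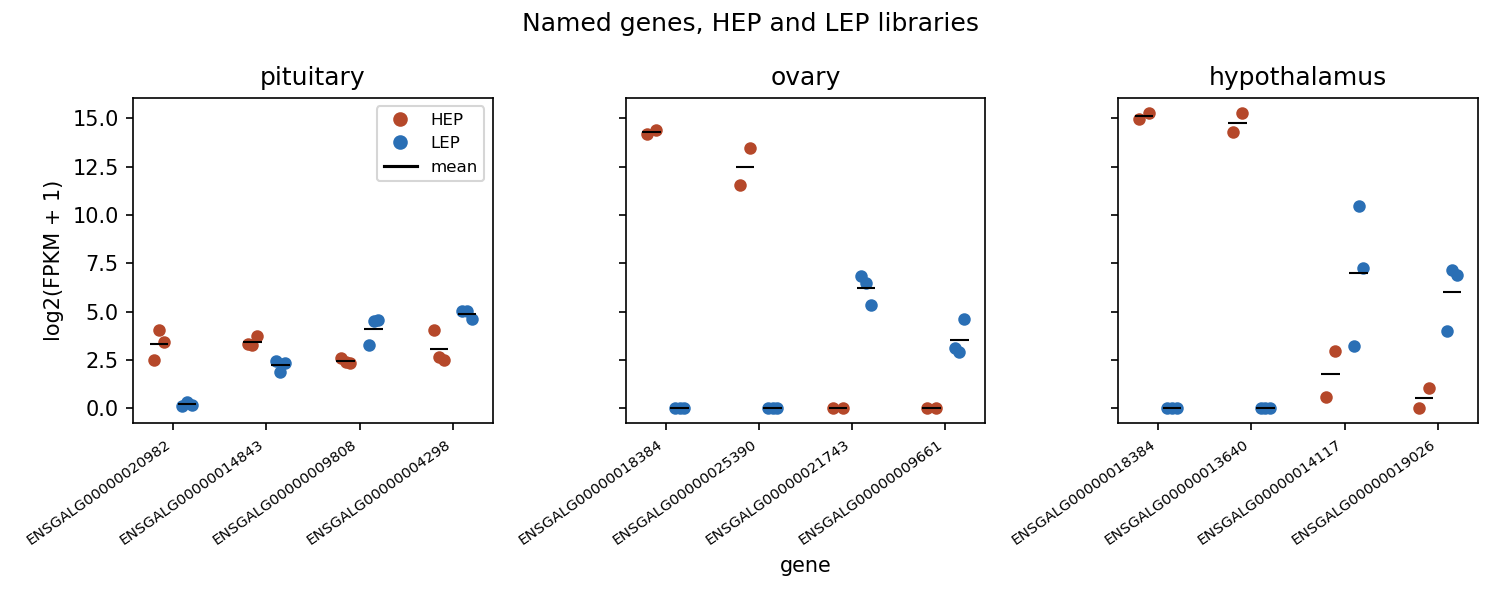
Expression as log2(FPKM + 1) (vertical axis) of the genes named for HEP against LEP in each tissue, with 1 point per library and a line at the group mean. In the pituitary, ENSGALG00000020982 reaches 4.58 to 15.35 FPKM in HEP and at most 0.27 FPKM in LEP, while ENSGALG00000018384 is listed at 0 in all LEP ovary and hypothalamus libraries.

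In the ovary, 3 genes were higher and 1 was lower in HEP hens, and each of the 4 was listed at 0 throughout 1 group. ENSGALG00000018384 was listed at 18612 and 21880 FPKM in the HEP ovaries and at 0 in the 3 LEP ovaries (adjusted p = 3.62e-07). ENSGALG00000025390 was listed at 2955 and 11419 FPKM in HEP and at 0 in LEP (adjusted p = 0.00081). In the pituitary this gene switched within groups, at 11376, 0 and 3759 FPKM in HEP and at 8038, 0 and 0 FPKM in LEP. ENSGALG00000021743 was listed at 0 in both HEP ovaries and at 113, 87.9 and 39.7 FPKM in the LEP ovaries (adjusted p = 0.0137), and at 0 in all pituitary and hypothalamus libraries. ENSGALG00000009661 was listed at 0 in HEP and at 7.79, 6.67 and 23.5 FPKM in LEP, and did not pass (adjusted p = 0.901). It passed only in the fit of all 16 libraries (adjusted p = 0.00157), where the pituitary and hypothalamus libraries, at no more than 0.33 FPKM, add almost no spread. Over its alternatives the adjusted p lay between 0.00157 and 1.00.

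Of 12326 ovary genes tested with limma, 172 had an unadjusted p under 0.05, where 616 are expected by chance. The 4 genes that passed all belong to the 98 ovary genes that switch between 0 and at least 10 FPKM. ENSGALG00000021743 did not pass without HEP 1 (adjusted p = 0.107), HEP 3 (adjusted p = 0.114) or LEP 4 (adjusted p = 0.0819), nor ENSGALG00000025390 in the fit of all 16 libraries (adjusted p = 1.00). The number of genes past the threshold was 12 without HEP 1, 8 without HEP 3, 7 without LEP 5 and 10 without LEP 6.

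In the hypothalamus, 5 genes were higher and 15 lower in HEP hens. In this fit the p values are those of a normal distribution. The SE was thus taken from the trend over all genes and not from a gene's own libraries. The SE, the p values and the number of genes called therefore do not measure a gene's own spread. ENSGALG00000018384 was listed at 31851 and 39942 FPKM in HEP and at 0 in the 3 LEP libraries (adjusted p = 7.41e-38), the same pattern as in the ovary. It was listed at 0 in all 6 pituitaries. ENSGALG00000013640 was listed at 19895 and 39840 FPKM in HEP hypothalami and at 0 in LEP hypothalami (adjusted p = 1.05e-34), while in pituitary and ovary it stood at 1.21 to 18.86 FPKM in every library of either group. For both genes the adjusted p depends on the fit, and was 0.000487 with quantile normalization, 0.00151 with no trend and 0.0236 without HEP 1, the highest of their alternatives. No gene lower in HEP passed without overlap of the libraries. The nearest were ENSGALG00000014117, at 0.52 and 6.96 FPKM in HEP and 8.48, 1389 and 153 FPKM in LEP (log2 difference -5.18, SE 1.38, adjusted p = 0.0701), and ENSGALG00000019026, listed at 0 and 1.08 FPKM in HEP and at 15.1, 144 and 120 FPKM in LEP (adjusted p = 0.394). The difference of ENSGALG00000014117 was -0.25 without the 3 hypothalamus libraries with few genes (adjusted p = 0.874) and -3.45 without LEP 5 (adjusted p = 1.00). It passed with a pseudocount of 0.1 (adjusted p = 0.0450), median-ratio scaling (adjusted p = 0.0277), without HEP 3 (adjusted p = 0.0124) and without switching genes (adjusted p = 0.0135), over a range of 0.0124 to 1.00 for all its alternatives. ENSGALG00000019026 passed in the fit of all 16 libraries (adjusted p = 0.0119), where the pituitary and ovary libraries, at no more than 0.52 FPKM, add almost no spread. Without the 3 libraries with few genes it passed too, but only HEP 3 and LEP 4 remain, with 1.08 and 15.1 FPKM. The difference there is -2.95 instead of -5.51. The range over its alternatives was 0.00217 to 1.00.

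Of 10703 hypothalamus genes tested with limma, 334 had an unadjusted p under 0.05, where 535 are expected by chance, and 18 of the 20 genes past the threshold switch between 0 and at least 10 FPKM. So do 5089 of the genes tested (47.5%), against 0.973% in the pituitary and 0.795% in the ovary, and without the 3 libraries with few genes 55 hypothalamus genes switch. The fit without switching genes, which drops 18 of the 20 by rule, kept 5614 genes and gave 0 higher and 5 lower, 2 of them among the 20. The median log2 difference over all genes was 0.40, and 0.19 after median-ratio scaling. Quantile normalization left 2 genes higher and 0 lower. Leaving out a library gave 3 genes without HEP 1, 85 without HEP 3, 2 without LEP 4, 35 without LEP 5 and 25 without LEP 6. Without LEP 6, 14 genes were higher and 11 lower, with 10 of the 20 kept. With the 3 libraries with few genes left out, a single HEP and a single LEP hypothalamus remain, and the fit of 13 libraries, which takes their spread from the other groups, gave 31 genes higher and 9 lower. ENSGALG00000018384 and ENSGALG00000013640 passed in each of these fits except the one without switching genes, which leaves them out.

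Across the 3 tissues, the mean HEP minus LEP difference passed for 2 genes higher in HEP, ENSGALG00000018384 (adjusted p = 8.90e-12) and ENSGALG00000013640 (adjusted p = 7.39e-05), and for 1 lower, ENSGALG00000021743 (adjusted p = 0.000455). All 3 are genes listed at 0 in whole groups, with the values given for ovary and hypothalamus. Such groups add no spread to the estimate of their error, and the tissues of a hen count as nearly independent in these p values. Each mean is carried mainly by part of the tissues. ENSGALG00000018384 is at 0 in every pituitary, and ENSGALG00000021743 is above 0 only in LEP ovaries. ENSGALG00000013640 stands at 1.21 to 18.86 FPKM in every pituitary and ovary, against 19895 and 39840 FPKM in the HEP hypothalami. In the limma fit, 559 of 12648 genes had an unadjusted p under 0.05. Leaving out hen 1, 3, 4 or 6 gave 20, 323, 315 and 5 genes.

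The HEP effect differed between pituitary and ovary for 4 genes, between pituitary and hypothalamus for 3, and between hypothalamus and ovary for 2. ENSGALG00000018384 differed between pituitary and ovary (adjusted p = 5.29e-09) and between pituitary and hypothalamus (adjusted p = 2.57e-09), being listed at 0 in the pituitary. ENSGALG00000013640 differed between pituitary and hypothalamus (adjusted p = 5.27e-05) and between hypothalamus and ovary (adjusted p = 0.000141). ENSGALG00000021743 differed between pituitary and ovary (adjusted p = 4.37e-05) and between hypothalamus and ovary (adjusted p = 0.000141). ENSGALG00000020982 differed in pituitary against ovary and against hypothalamus (log2 difference 3.10, SE 0.45, adjusted p = 0.0407 for each). With hen as block, ENSGALG00000020982 did not pass in either contrast (log2 difference 2.75, SE 0.39, adjusted p = 0.222), and 2 of the 4 genes passed for pituitary against ovary. It also did not pass against ovary without hen 3, 4, 5 or 6 (adjusted p between 0.546 and 0.758), nor against hypothalamus without hen 5 (adjusted p = 0.670) or hen 6 (adjusted p = 0.698), where the log2 difference was 3.04 to 3.17 and the SE 0.56 to 0.58. Without the 3 hypothalamus libraries with few genes it passed in neither contrast. The log2 difference was still 3.10 in both (SE 0.48 against ovary and 0.64 against hypothalamus). Against ovary, none of the libraries left out enters the difference. Against hypothalamus, the gene is listed at 0 in the libraries left out. These genes are listed at 0 in every library of some groups, which add no spread to the estimate of their error.

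Genes enriched in a tissue were compared as groups. Among 134 pituitary-enriched genes, 40 had a positive and 94 a negative HEP minus LEP difference in the pituitary. Their median was -0.11, against -0.030 for all 11820 genes tested there (camera, adjusted p = 0.0794, and adjusted p = 0.963 with an estimated correlation). The most abundant of the 134, ENSGALG00000000249, stood at 19683 ± 2431 FPKM in HEP (SD, n = 3) and 39338 ± 13858 FPKM in LEP (SD, n = 3), without overlap (log2 difference -0.95, limma adjusted p = 1.00). An exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. ENSGALG00000028564 stood at 22452 ± 1539 and 23714 ± 6541 FPKM. Among 368 ovary-enriched genes, 181 were positive and 187 negative in the ovary (camera, adjusted p = 0.455), and among 183 hypothalamus-enriched genes 108 were positive and 75 negative in the hypothalamus, with a median of 0.20 against 0.40 for all genes tested there, so that camera places this set lower (adjusted p = 0.398). No gene of the 3 sets passed within its tissue. For the pituitary and ovary sets this was fixed beforehand and is no result. No pituitary gene passed at all, and each ovary gene that passed was listed at 0 throughout a group, which the no-overlap rule of the sets bars. Of the 47 pituitary-enriched genes measured in the hypothalamus, 24 were positive and 23 negative, with a median of 0.03 and a mean of -0.40. This set passed as lower only relative to the other genes (camera, adjusted p = 0.0334), and not with an estimated correlation (adjusted p = 0.989). Both hypothalamus tests rest on 5 libraries of which 3 list few genes.

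The HEP minus LEP differences of pituitary and ovary correlated across 11085 genes with Pearson r = 0.358 and Spearman rho = 0.402 in the 5 hens with all tissues. The other 9 splits of these hens gave r between -0.046 and 0.219. The exact permutation p was 0.1 for either coefficient, the smallest that 10 splits allow, and 0.3 after adjustment over the 3 pairs of tissues. For pituitary and hypothalamus r was 0.038 and rho 0.063 over 10202 genes (exact permutation p = 0.3 and 0.4, adjusted p = 0.45 for r). For hypothalamus and ovary r was 0.023 and rho 0.015 over 10227 genes (exact permutation p = 0.9 and 0.7, adjusted p = 0.9 for r). In the hypothalamus, 1 of the 2 HEP and 2 of the 3 LEP libraries list few genes and correlate with the other libraries of the tissue at 0.577 to 0.709, so the low r of these pairs cannot be set against 0.358. Genes are not independent replicates, so only the splits of hens serve as reference.

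**Figure D3:**
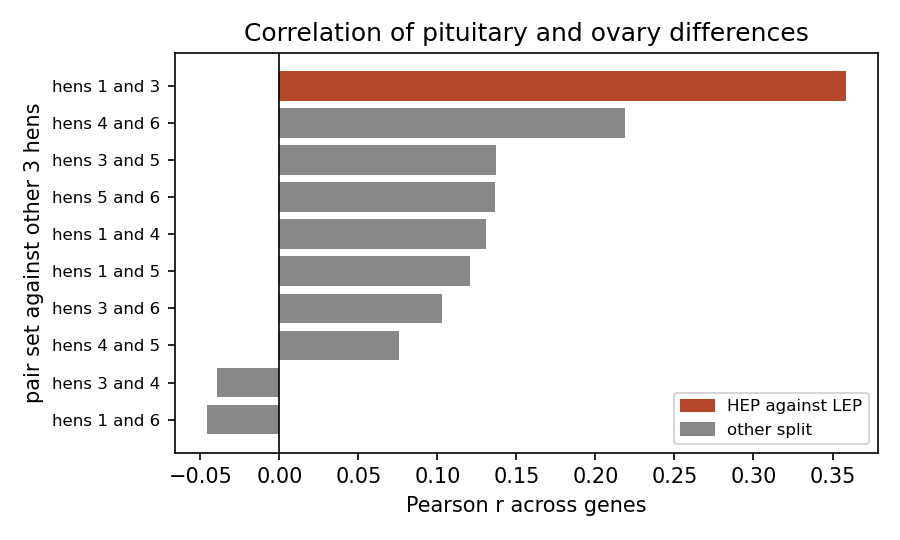
Pearson r across 11085 genes (horizontal axis) between pituitary and ovary differences, for each of the 10 splits of 5 hens into a pair and the other 3 (vertical axis). HEP against LEP gives 0.358, the highest other split, hens 4 and 6, gives 0.219.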

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

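The tests in this part were chosen after the results were seen, except that the contrasts between tissues were planned. The HEP effect differed between tissues for 4 named genes, though with hen as block ENSGALG00000020982 no longer passed (adjusted p = 0.222). For pituitary against ovary these were ENSGALG00000018384 (adjusted p = 5.29e-09), ENSGALG00000021743 (adjusted p = 4.37e-05) and ENSGALG00000020982 (adjusted p = 0.0407). For pituitary against hypothalamus they were ENSGALG00000018384 (adjusted p = 2.57e-09), ENSGALG00000013640 (adjusted p = 5.27e-05) and ENSGALG00000020982 (adjusted p = 0.0407). For hypothalamus against ovary they were ENSGALG00000013640 and ENSGALG00000021743 (adjusted p = 0.000141 for each).

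Of these, ENSGALG00000018384, ENSGALG00000013640 and ENSGALG00000021743 switch between 0 and high values, as do all 4 genes called in the ovary and 18 of 20 in the hypothalamus, where 47.5% of the genes tested switch. If failed estimates at abundant genes were the source, zeros should become more frequent at high levels. In the 13 libraries with most genes above 0, a gene was listed at 0 in 8.15% of cases where the other libraries of the tissue averaged at least 1000 FPKM, against 0.461% at 10 to 100 FPKM. Failed estimates may account for part of the calls. However, an abundant gene truly off in some hens would count in the same way, the called genes included, so this share does not single out failed estimates. Reads per gene are unknown, so a high FPKM need not mean many reads, and zeros from few reads are not set apart either. By FPKM level alone, failed estimates fit ENSGALG00000021743 less well, which reaches no more than 113 FPKM. Egg production stays open: 5 ovary genes were at 0 in all libraries of 1 group and above 0 in all of the other for HEP against LEP, while another split of the 5 ovaries gave 7, and the splits are too few for a share under 0.05.

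The 3 hypothalamus libraries with few genes above 0 were HEP 1, LEP 5 and LEP 6. If single reads set the lowest values above 0, shallower sequencing would raise these values. The 1st percentile in the 3 libraries was at most 0.026 FPKM, against at least 0.042 FPKM in the other hypothalamus libraries. Whole reads could not be recovered from the low values and depth is unknown, so this does not decide about shallower sequencing. Egg production does not explain the 3 libraries, as 1 of the 3 is HEP and 2 are LEP. A candidate explanation is few starting molecules or loss of cDNA, by which genes drop out partly independently. Shallower sequencing would also make genes drop out partly independently, so the shares that follow cannot tell these apart. At 10 to 30 FPKM in the other hypothalamus libraries, 10.6% of genes were at 0 in all 3, against 5.01% if independent and 34.8% if the same genes were lost. At 300 FPKM and above, the shared share of 5.58% lay nearer to the 7.57% of the same genes being lost.

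Other splits of the samples were counted for each comparison. In the pituitary the real split gave 0 genes, so all 10 splits of the 6 libraries gave as many, and the highest other gave 4. In the ovary 4 of 10 splits gave at least the real 4 genes (highest other 8), and in the hypothalamus 4 of 10 gave at least the real 20. The highest other hypothalamus split, 2152 genes, sets HEP 3 and LEP 4 against the 3 libraries with few genes and points to that structure. For the mean of tissues 5 of 10 splits of the hens gave at least the real 3 genes, with 2428 for hens 1, 5 and 6, the hens of those libraries. With 10 splits no share under 0.05 can be reached. At an unadjusted limma p under 0.05, the real pituitary split gave 244 genes and the others 112 to 1548. The highest set HEP 1, HEP 3 and LEP 4 against the rest. The real ovary split gave 172 genes and the others 151 to 1929, highest for LEP 4 with LEP 5. Some other splits thus part the libraries of a tissue more strongly than the production groups do. For the tissue contrasts, only the real split, 1 of 100, gave 2941 genes for pituitary against ovary (highest other 1620) and 4679 for pituitary against hypothalamus (highest other 2813). For hypothalamus against ovary 1 of 60 gave 5758 (highest other 2). The shares, 0.01, 0.01 and 0.0167, are the smallest that so many splits allow, so chance is unlikely but not excluded. Among the splits that part all 5 hens with all tissues, the highest others were 1, 2813 and 2.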

How the results depend on the processing

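Of 137 alternatives for counts and correlations, 84 stayed within 1.5 times the main count or kept the direction, 53 moved and 0 reversed. A count can only stay or move, so the 0 reversed says nothing about counts. Of 394 for named genes and sets, 363 kept direction and side of the threshold, 16 no longer passed, 15 newly passed and 0 reversed. Settings without the switching genes or the 3 hypothalamus libraries with few genes, and the set tests, were added after the data were seen. The gene lists by symbol gave no values. A pseudocount of 0.1 gave 1 gene in the pituitary, 41 in the hypothalamus and 1890 for pituitary against ovary. All 16 libraries in a single fit gave 1 gene in the pituitary and 3 in the hypothalamus. In the hypothalamus no filter, a filter at 5 FPKM, quantile normalization and no trend each gave 2 genes, and array weights 13. No filter gave 4 for the HEP effect in hypothalamus minus ovary. Hen as replicate block gave 2 genes for the HEP effect in pituitary minus ovary, both among the main 4, and ended the call of ENSGALG00000020982 in both contrasts (adjusted p = 0.222). It changed no other call of a named gene.

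Leaving out switching genes reduced the genes tested from 10703 to 5614 in the hypothalamus and from 12648 to 7470 in the model of all libraries. This removes passing genes by the change itself, so their loss is no test of them. Without them, counts became 1 in the pituitary, 0 in the ovary, 5 in the hypothalamus, 0 for the mean of tissues, and 1, 1 and 0 for the HEP effect in pituitary minus ovary, pituitary minus hypothalamus and hypothalamus minus ovary. Without the 3 hypothalamus libraries they became 40 in the hypothalamus, 24 for the mean of tissues, 2, 28 and 28 for these 3 contrasts, and 4724 for pituitary against ovary.

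Leaving out a replicate gave 1 to 4 genes in the pituitary, 4 to 12 in the ovary, 2 to 85 in the hypothalamus and 3 to 323 for the mean of tissues. The HEP effect gave 3 to 7 genes for pituitary minus ovary, 2 to 752 for pituitary minus hypothalamus and 2 to 679 for hypothalamus minus ovary. Counts above 300 arose without hen 3 or hen 4, the only hens with a hypothalamus library listing most genes, which leaves libraries with few genes on that side only. The tissue contrasts gave 2336 to 2700 for pituitary against ovary, 2542 to 5882 for pituitary against hypothalamus and 3127 to 6351 for hypothalamus against ovary. The lone library left by some of these fits is assumed to vary like the other groups. The cause of the other shifts was not tested. The correlation of pituitary and ovary differences was 0.296 with a pseudocount of 0.1 and 0.39 with a filter at 5 FPKM. Depth is unknown, so its effect on these values cannot be given.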

Other observations

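The tests on hen pairing and the values of single hens were chosen after the data were seen. The tests of scaling and of different hens were fixed before their results were seen, while the requirement on deviations within hens, and the rule that a scaling test moving r by under 0.05 decides nothing, were added afterwards.

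The correlation of 0.358 between pituitary and ovary differences was 0.359 with median-ratio scaling, against 0.220 for the highest other split, but this scaling moved r by at most 0.0089 in any of the 10 splits and so decides nothing about scaling. With different hens in the pituitary and ovary difference, the 24 choices gave a median r of 0.024, with 12 above 0, a range of -0.237 to 0.270, and up to 0.348 in size for 36 choices with a difference within a group. The median rests on hen 2, which is not among the 5 hens behind 0.358: the 12 choices without its pituitary gave a median of 0.133 with 8 above 0, the 12 with it -0.0080 with 4 above 0. A shared state of single hens stays open, since deviations correlated between these tissues with r of 0.143 and 0.208 in HEP hens 1 and 3, which mirror each other in the ovary as its only HEP libraries, and of -0.060, 0.061 and -0.034 in LEP hens 4, 5 and 6. Egg production cannot be told apart from an unlabelled batch that follows the groups, the exact permutation p being 0.1 with 10 splits.

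Whether the pituitary and ovary of a hen share variation was asked by counting genes that follow each other over 5 hens with r above 0.9. The count was set against the 120 ways to pair the hens, at 3 minimum SDs with and without switching genes (6 permutation tests). Group means were not removed and pairings cross HEP and LEP, so a group difference shared by both tissues also favours the true pairing. The true pairing gave 26 genes, against at most 23 in other pairings, at a minimum SD of 0.5 (permutation p = 0.0083, adjusted p = 0.025), where 0.0083 is the smallest that 120 pairings give. It gave 74 genes against up to 142 at 0.3 (permutation p = 0.108) and 8 against up to 10 at 1 (permutation p = 0.0583), so the result depends on the SD chosen.

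ENSGALG00000023622 stood at 625 FPKM in the LEP 5 ovary and at 21.4 to 49.1 FPKM in the other ovaries, and at 40.4 FPKM in the LEP 5 pituitary against 2.54 to 6.07 FPKM in the other pituitaries. ENSGALG00000026540 stood at 0.88 FPKM in the LEP 6 ovary and 0.63 FPKM in the LEP 6 pituitary, against 5.68 to 10.93 and 10.1 to 18.38 FPKM in the other hens. ENSGALG00000025698, 1 of the 3 genes that take most of the FPKM, stood at 239313 FPKM in pituitary HEP 2 and 355739 FPKM in LEP 6, and at 15863 to 20881 FPKM in the other pituitaries. In the ovary it stood at 660677 FPKM in LEP 4 and 465195 FPKM in LEP 5, and at 46246.5 to 175723 FPKM in the other ovaries.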
